A study of Mus musculus with 4 samples.

How the data were processed

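RNA was measured in 4 libraries of sorted adipocyte precursors, 2 WT and 2 labelled Per3 KO. Per the labels' protocols, cells were lysed directly after the sort, total RNA was extracted with a micro-scale column kit and cDNA was primed with oligo-dT, which reads polyadenylated transcripts. Each library has a table of 20207 genes, and groups and replicate numbers were taken from the sample titles.

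The deposited tables hold an estimated count of reads per gene, as made by the authors and not normalised, per the file headers. Between 8.85% and 12.0% of genes had values that were not whole (tolerance 1e-09), and values above 9999 were kept to 4 significant digits. The deposited RPKM column scales the reads by transcript length and library total, per the file headers. The deposited Z-score is a score that centres and scales RPKM within a library, and the deposited RMS-normalised column is a ratio of RPKM to the root mean square of all genes. These 2 columns were not used in tests. STAR 2.4.0, Cufflinks, Cuffdiff 2.2.1 and the mouse build mm9 are named in the submitters' processing notes, without their roles. How the counts were made, the annotation, the treatment of reads that match several genes and the use of strand are not given in the sources used here, so near-identical copies and overlapping genes are uncertain. Row order differed between tables, and genes were joined by symbol. No symbol occurred more than once in a table. For 486 genes the coordinates differed between tables, Per1, Pigp and Mx1 among the named genes.

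The design fixed before the data were examined assumed FPKM values and gave a second branch for counts. The tables held counts, so that branch became the main test and limma on RPKM became an alternative. Counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 12494. Libraries were scaled by TMM factors of 1.03, 0.832, 1.04 and 1.12 for WT 1, WT 2, Per3 KO 1 and Per3 KO 2. The groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, prior count 0.125, genotype as the only term, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are rounded counts over the TMM-scaled totals, and the standard error of a log2 fold change is its size over the square root of the F statistic. A floor of 3 reads per library was used for genes at 0 in a group. It covers counting error only, since reads without molecular identifiers are not independent molecules.

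Before the data were examined, 27 gene lists were fixed, and 25 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists. An estimated correlation and fry were the alternatives. Named genes followed a rule fixed at the same time. It took Per3, Klf15, Ly6a, Ptprc and Pecam1 always, and up to 12 genes per direction with a mean RPKM of at least 5 and both KO-labelled libraries on the same side of both WT libraries. Genes past the threshold were to come first by fold change, and the rest by unadjusted p, named as not passing. It also took up to 3 members per list by p, or up to 6 that passed, and 8 core clock genes. Names outside the rule are given as chosen after the values were seen, and Eno1, Npas2, Nfil3 and the liver genes belong to these.

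Alternatives fixed beforehand were limma on log2(RPKM + pseudocount) for genes with a mean RPKM of at least 1, with pseudocounts of 0.1 and 1, TMM or quantile scaling, no variance trend or a robust fit, no filter, a mean RPKM of at least 5, DESeq2 1.42.0, the replicate number as a block and leaving out each library. Limma with a pseudocount of 0.5 was the first branch of the fixed design, for FPKM values. It became an alternative once the tables were seen to hold counts. Added after seeing the data were DESeq2 size factors in edgeR and a crossed block. In fits with 3 libraries the lone library of a group is assumed to vary like the other group. The choice between summing and selecting rows of the same symbol did not apply.

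The pipeline was tested on simulated counts with the means, totals and spread of these libraries. For the comparison of KO-labelled with WT libraries, edgeR recovered 9.38% of 4-fold and 64.6% of 16-fold changes with 12 false calls among 12052 genes. DESeq2 recovered 26% and 78% with 81 false calls among 12492 genes, and limma 12.9% and 64.8% with 19 false calls among 11058 genes. Limma ran on CPM of the simulated counts with a mean of at least 1, and not on RPKM as in the data. With a low spread, edgeR recovered 99% and 100% with 14 false calls among 12439 genes. The depth of 27950825 to 64964443 reads sets a floor of 0.0412 to 0.129 CPM per library. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 162 to 1079), so no library was taken for a second copy of another. This does not show whether replicates are biological or technical.

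The reference at hand is another build than mm9, so its coordinates were not used. Its GENCODE M21 transcripts served only to align Eno1 with Gm5506, which a RefSeq synonym table of GRCm38.p6 lists as Eno1b. Figures were drawn with matplotlib 3.10.9.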

Results

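Transcript levels were measured by RNA sequencing in adipocyte precursor cells, the progenitors in adipose tissue that give rise to fat cells. The cells were sorted from freshly dissociated adipose tissue of C57BL/6 mice as Sca1+ CD45- CD31-, a gate that keeps Sca1-bearing stromal cells and leaves out blood and endothelial cells. There were 4 libraries, 2 from wild-type (WT) littermates and 2 labelled as knockout (KO) for Per3, a period gene of the circadian clock, all from young mice at zeitgeber time 2, that is 2 h after lights on. Total gene reads were 37101227 in WT 1, 27950825 in WT 2, 40003115 in Per3 KO 1 and 64964443 in Per3 KO 2. The files listed 20207 genes, of which 6337, 6750, 6058 and 5436 had no read in these libraries in the same order. Log2 CPM of the WT pair correlated across genes with r = 0.794 and that of the KO-labelled pair with r = 0.855. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

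Per3 (mm9 chromosome 4, 150377764 to 150418731) was not lower in the libraries labelled Per3 KO. Its reads were 121 in WT 1, 170 in WT 2, 193 in Per3 KO 1 and 768 in Per3 KO 2. The normalised level was 5.23 ± 2.94 CPM in WT and 7.60 ± 4.16 CPM in the KO-labelled libraries (SD, n = 2 each). The log2 fold change was 0.54 with a standard error of 0.83 (edgeR adjusted p = 1.00), and it was -0.17 without Per3 KO 2. The count covers the whole gene, and the labels do not say which part was altered, so it does not check a deletion of part of the gene. Libraries are therefore called KO-labelled, and every direction below is that of the KO-labelled libraries relative to WT.

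The gate's own genes were read next. Ly6a, which encodes Sca1 (chromosome 15, 74825307 to 74828318), was among the abundant transcripts, at 8436 ± 8257 CPM in WT and 2950 ± 1156 CPM in KO-labelled libraries (SD, n = 2). Its log2 fold change of -1.52 ± 1.01 (SE) became 0.19 without WT 2. Ptprc, which encodes CD45, had 0, 5, 4 and 50 reads in WT 1, WT 2, Per3 KO 1 and Per3 KO 2 and was too low to test. Pecam1, which encodes CD31, had 79, 206, 279 and 378 reads and a log2 fold change of 0.13 ± 0.92, which turned to -0.57 without WT 1 and to -0.11 without Per3 KO 1. Fibroblast and matrix transcripts were abundant in both groups. Col1a1 stood at 33434 ± 16197 CPM in WT and 25844 ± 1733 CPM in KO-labelled libraries, and Sparc at 75209 ± 20901 and 53703 ± 4237 CPM (SD, n = 2). Col1a1 and Sparc were chosen after their values were seen.

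The main comparison asked how the transcriptome of the KO-labelled precursors differs from that of WT littermates. The clearest separation of single genes was Gm5506, a near-identical copy of the glycolytic enzyme gene Eno1 (chromosome 18, 48204989 to 48208037). It had 17.92 and 1.996 reads in the WT libraries against 4782 and 6181 in the KO-labelled ones, a log2 fold change of 8.39 ± 0.90 (SE). Reads of Gm5506 and Eno1 can be placed on either copy, so the level of Gm5506 alone is uncertain. Among the higher genes that the rule took by direction, the next by p were Max, the partner of Myc proteins, at 15.9 ± 5.58 against 61.6 ± 8.46 CPM, and the non-coding RNA Rian of the imprinted Dlk1-Dio3 cluster, at 19.3 ± 2.71 against 65.3 ± 10.6 CPM (SD, n = 2). On the lower side were Tnnc2, a troponin of fast skeletal muscle, at 41.8 ± 31.9 CPM in WT against 4.96 ± 0.703 CPM, and the neuropeptide gene Nmb, at 25.1 ± 16.9 against 2.93 ± 1.18 CPM.

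None of these genes passed the main test. Of 12494 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.293, for Gm5506. At an unadjusted p under 0.05 there were 257 genes, 148 higher and 109 lower, where chance alone gives 624.7. DESeq2 called 14 genes, 7 higher and 7 lower, and limma on log2(RPKM + 0.5) called 1, Gm5506. Tnnc2 passed with DESeq2 (adjusted p = 0.026) and in edgeR without a filter (0.0314), 2 of 17 alternatives whose adjusted p reached from 0.026 to 1. Both KO-labelled libraries lay above both WT libraries for 1819 genes and below for 1434, together 26.0% of those tested, against 33.3% expected by chance for 2 against 2. The spread between libraries of a group was large, with a common biological coefficient of variation of 0.742.

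The remaining genes of the rule, none past the threshold, had log2 fold changes from 1.27 to 3.09 on the higher side. They were Nr1d1 (3.09), the mitotic cyclin Ccnb2 (2.52), the tyrosine catabolism enzyme Fah (1.88), the chemokine Cxcl3 (1.54), the plasminogen activator Plau (1.49), the Mediator subunit Med20 (1.33), Crip2 (1.32), the RNA helicase Ddx47 (1.28) and the chaperone clusterin, Clu (1.27). On the lower side they were the Mediator subunit Med11 (-2.56), Zbtb8os (-1.78), the tRNA splicing endonuclease subunit Tsen15 (-1.74), Znrd1 (-1.60), AI462493 (-1.57), Pigp of glycosylphosphatidylinositol anchor synthesis (-1.50), 1110005A03Rik (-1.40), the sulfotransferase Sult1a1 (-1.36), 9130401M01Rik (-1.35) and the presenilin Psen2 (-1.29). Each had an edgeR adjusted p of 1.00. With a library left out, 12 of the 24 genes that the rule took by direction moved by over 0.585 on the log2 scale, mostly without WT 1 or WT 2. Without WT 1 and without WT 2 the values were 7.47 and 2.13 for Nr1d1, 3.22 and 1.21 for Fah, -3.06 and -1.77 for Med11, -2.35 and -0.82 for Zbtb8os, -1.91 and -0.91 for Pigp, -2.16 and -0.65 for Znrd1, -2.18 and -0.49 for AI462493, -3.69 and -1.95 for Tnnc2, -3.66 and -2.16 for Nmb and 10.15 and 7.73 for Gm5506. Ccnb2 was at 4.24 without WT 1 and 1.63 without Per3 KO 1, and Cxcl3 at 0.59 without Per3 KO 1.

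Klf15, a Krüppel-like factor that promotes adipocyte differentiation (chromosome 6, 90412620 to 90425203), was close to the detection limit. It had 3.943 and 1.99 reads in WT 1 and WT 2 and 36 and 106 in Per3 KO 1 and Per3 KO 2, or 0.0952 ± 0.013 against 1.16 ± 0.414 CPM (SD, n = 2). The log2 fold change of 3.57 had a standard error of 2.00 (edgeR adjusted p = 1.00).

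Of 17 clock genes tested, 7 were above both WT libraries in both KO-labelled libraries, 3 were below both, and the others overlapped, where chance alone gives 33.3% apart in either direction. None passed the main test. Tef, a PAR bZIP output factor, stood at 11.6 ± 4.05 CPM in WT and 55.3 ± 7.26 CPM in KO-labelled libraries, Dbp of the same family at 3.17 ± 1.35 and 17.3 ± 1.12 CPM, and Nr1d2, which encodes REV-ERBβ, at 21.3 ± 5.93 and 59.9 ± 10.1 CPM (SD, n = 2). Arntl, which encodes the activator BMAL1, was at 33.1 ± 5.64 CPM in WT and 12.5 ± 2.53 CPM in KO-labelled libraries. The log2 fold changes were 2.26 ± 0.53 for Tef, 2.45 ± 0.69 for Dbp, 1.50 ± 0.50 for Nr1d2 and -1.41 ± 0.52 for Arntl (SE).

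**Figure D1:**
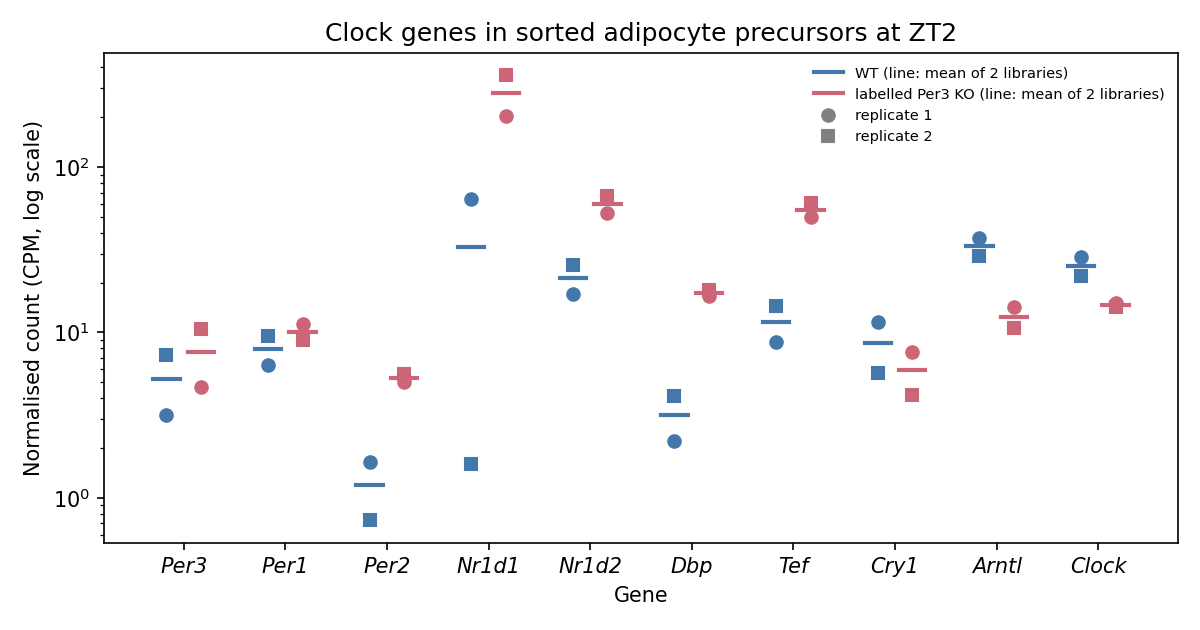
Normalised counts (CPM, log scale) of Per3 and 9 further clock genes in each library, with circles for replicate 1, squares for replicate 2 and lines for the mean of the 2 libraries of a group. Both KO-labelled libraries lie above both WT libraries for Nr1d1, Nr1d2, Dbp, Tef and Per2 and below both for Arntl and Clock, while Per3, Per1 and Cry1 overlap.

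Over the whole list 12 genes had a positive and 5 a negative log2 fold change, and 4 had an unadjusted p under 0.05. The 5 negative ones were Arntl, its partner Clock (-0.79), Npas2 (-1.29), the repressor Cry1 (-0.54, or 0.07 without WT 1) and Nfil3 (-0.63). Among the positive ones, Nr1d1 (3.09 ± 1.37) was at 64.3, 1.59, 203 and 359 CPM in WT 1, WT 2, Per3 KO 1 and Per3 KO 2, Per2 had 2.15 ± 1.11 and Per1 0.36 ± 0.66 (SE). None passed over all genes tested, and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.055 (edgeR). Nr1d1 passed over all genes in 3 of 17 alternatives, among them no filter (edgeR adjusted p = 0.0314) and without WT 1 (0.0312), with a range from 0.00626 to 1. As a list, the clock genes were higher in a camera test with a preset correlation of 0.01 (adjusted p = 0.014). With an estimated correlation the camera adjusted p was 0.682. The estimate was -0.0221, below the preset value, so correlation between members does not account for the loss of the call made at the preset correlation. The adjusted p was 0.0832 without WT 2 and 0.0612 without Per3 KO 1.

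Cell cycle genes had a positive log2 fold change in 19 of 21 tested, with a median of 0.95. Ccnb2 was at 4.94 ± 4.86 CPM in WT and 28.5 ± 18.6 CPM in KO-labelled libraries, the mitotic checkpoint kinase Bub1 at 0.0998 ± 0.0803 and 3.32 ± 2.27 CPM, and the mitotic kinase Aurka at 1.25 ± 1.70 and 6.60 ± 2.10 CPM (SD, n = 2). The list was higher by camera (adjusted p = 0.00891), with adjusted p = 0.682 with an estimated correlation. No member passed over all genes tested or adjusted over the list alone. The median CPM of the list was 14.0 in WT 1, 3.70 in WT 2, 20.7 in Per3 KO 1 and 8.08 in Per3 KO 2. The call was lost without WT 2 (adjusted p = 0.513), and without Per3 KO 1 the direction turned to lower (adjusted p = 0.792).

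Cholesterol synthesis genes had a positive log2 fold change in 12 of 16 tested, with a median of 0.44. Nsdhl was at 20.5 ± 19.4 CPM in WT and 52.0 ± 15.4 CPM in KO-labelled libraries, and squalene synthase, Fdft1, at 41.2 ± 30.7 and 79.8 ± 49.5 CPM (SD, n = 2). Lanosterol synthase, Lss, had 107, 0, 319 and 310 reads. The list was higher by camera (adjusted p = 0.0333), with adjusted p = 0.682 with an estimated correlation, and no member passed over all genes tested or adjusted over the list alone. Its median CPM was 78.8, 17.3, 77.5 and 45.6 in WT 1, WT 2, Per3 KO 1 and Per3 KO 2. Without WT 2 the direction turned to lower (adjusted p = 0.290), and without Per3 KO 1 the adjusted p was 0.792.

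**Figure D2:**
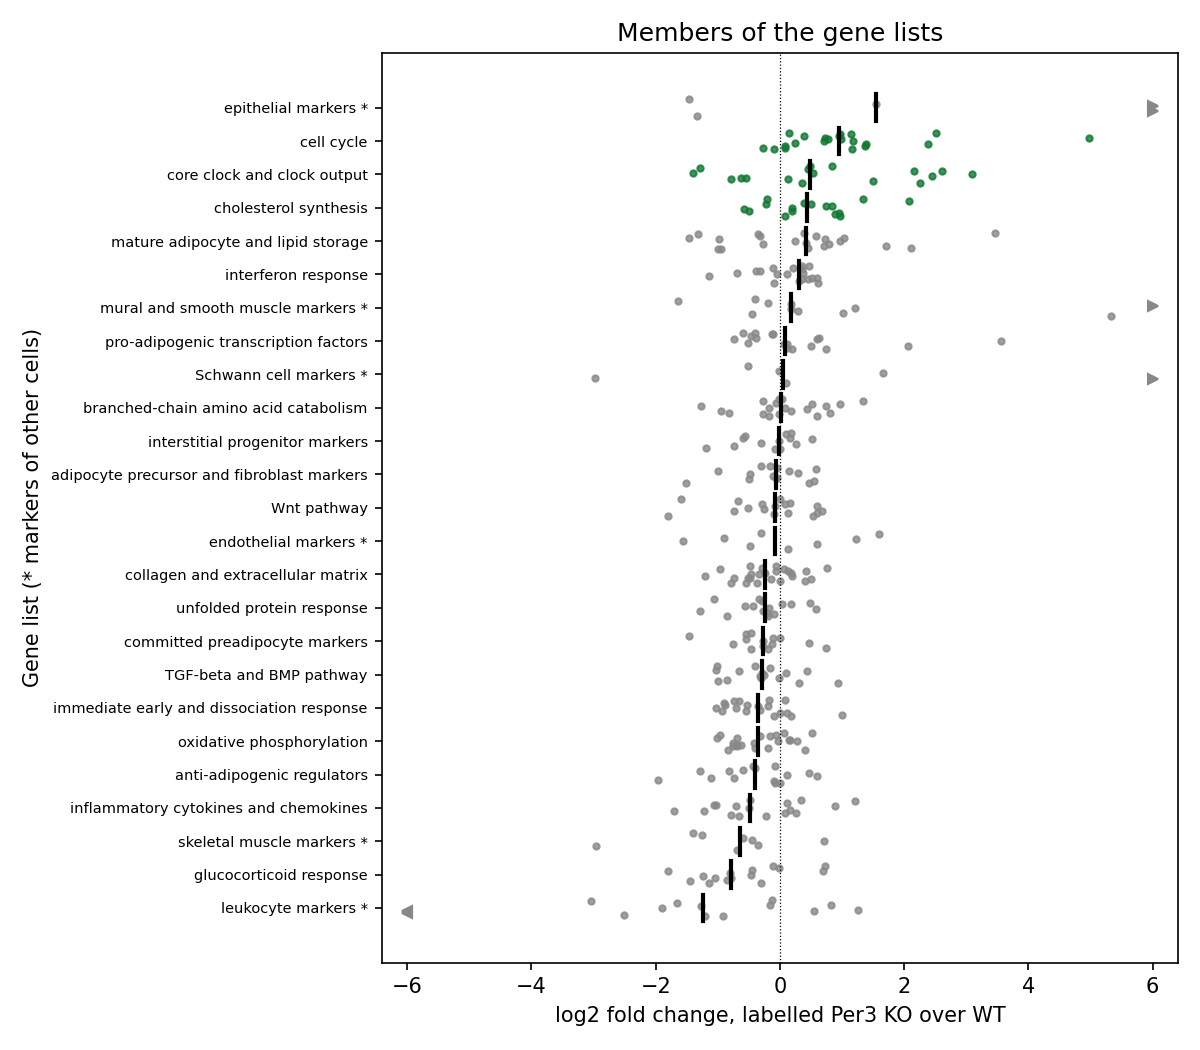
Log2 fold change (KO-labelled over WT) of each tested member of the 25 gene lists, with a bar at each list's median and triangles for members beyond the axis. Lists past the camera threshold with the preset correlation are in green, namely cell cycle, clock and cholesterol synthesis, with medians of 0.95, 0.49 and 0.44.

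No list of markers of other cells passed the main camera test. Leukocyte markers were lower in 11 of 14 tested (median -1.24, adjusted p = 0.058). Among them Cd52 had 28, 126, 0 and 0 reads, at least 54.1-fold lower against a floor of 3 reads per library, and S100a8 had 10, 35, 0 and 0, at least 15.5-fold lower. These bounds were 12.9-fold and 4.59-fold without WT 2, and 95.4-fold and 26.5-fold without WT 1. Cd74, the invariant chain of MHC class II, had the opposite sign, with 118, 110, 466 and 538 reads and a log2 fold change of 1.26 ± 0.75 (SE). Of the list, 3 genes lay above both WT libraries in both KO-labelled libraries and 3 below, against 33.3% expected by chance in either direction. The leukocyte list passed as lower in 5 of 18 alternatives, among them DESeq2 (adjusted p = 0.0202), no filter (0.0248), without WT 1 (0.000831) and without Per3 KO 1 (0.00555), and turned to higher without WT 2 (0.183), the highest being 0.697. Cd52 passed with DESeq2 alone of 16 alternatives (adjusted p = 0.0258, range to 1). Skeletal muscle markers were lower in 7 of 8 (median -0.65, adjusted p = 0.092), with Tnni2 at 5.67 ± 5.06 CPM in WT and 0.730 ± 0.470 CPM in KO-labelled libraries (SD, n = 2). That list passed in 5 of 18 alternatives, namely no filter (adjusted p = 0.0152), limma with quantile scaling (0.0368) and limma on log2(RPKM + 0.5) as such, with no trend or with a robust fit (0.0488 each), the highest being 0.682. Epithelial markers were higher in 3 of 5 (median 1.54, adjusted p = 0.0998). Cldn4 had 0, 0, 38 and 112 reads, at least 11.8-fold higher, and Cdh1 0, 0, 19 and 72, at least 6.98-fold higher, or 4.43-fold without Per3 KO 2. Cldn3 had the opposite sign, with 117, 30, 39 and 46 reads and a log2 fold change of -1.46 ± 1.50 (SE). The summed CPM of the epithelial list was 5.09, 1.50, 2.75 and 4.80 in WT 1, WT 2, Per3 KO 1 and Per3 KO 2. Mural markers were higher in 7 of 11 (median 0.18, mean 1.05, adjusted p = 0.145), and 4 of them lay above both WT libraries in both KO-labelled libraries and 0 below. Among these, Cnn1, a calponin of smooth muscle, had 0.9467, 0, 31.94 and 109.9 reads, and the pericyte gene Rgs5 had 2.955, 0, 51.97 and 173. Schwann cell markers were higher in 3 of 6 (median 0.04, mean 0.98, adjusted p = 0.735) and endothelial markers in 4 of 8 (median -0.09, adjusted p = 0.765). The endothelial mean was 0.04, opposite in sign to the median and the test. Medians of these lists were the same with genes at 0 in a group set at their bound. Only 3 mesothelial and 3 erythroid markers were tested, 2 higher and 1 lower in each, too few for a list test. The erythroid median of 0.55 and mean of -0.39 differed in sign.

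Adipogenic gene groups did not pass. Among pro-adipogenic transcription factors 10 of 18 tested had a positive log2 fold change (median 0.09, camera adjusted p = 0.564), with Cebpd at 42.6 ± 9.86 CPM in WT and 28.1 ± 3.08 CPM in KO-labelled libraries and Klf5 at 178, 0, 610 and 346 reads. Anti-adipogenic regulators were negative in 11 of 15 (median -0.41, adjusted p = 0.145), with Ddit3, which encodes CHOP, at 126 ± 96.9 and 51.9 ± 12.2 CPM and Foxo1 at 78.5 ± 59.0 and 36.3 ± 6.34 CPM. With a library left out, the log2 fold change ranged from -1.90 to -0.15 for Ddit3 and from -1.72 to -0.01 for Foxo1. Mature adipocyte and lipid storage genes were positive in 13 of 21 (median 0.42, adjusted p = 0.145). The triglyceride lipase Pnpla2 was at 9.31 ± 5.57 and 30.6 ± 13.3 CPM, the insulin-responsive glucose transporter Slc2a4 at 0.395 ± 0.254 and 4.42 ± 2.56 CPM and Thrsp at 2.16 ± 0.629 and 9.36 ± 5.83 CPM (SD, n = 2). Without WT 2 the direction turned for the anti-adipogenic list (adjusted p = 0.752) and for the mature adipocyte list (adjusted p = 0.850).

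Progenitor and matrix lists did not pass. Precursor and fibroblast markers were negative in 10 of 15 (median -0.07, camera adjusted p = 0.572), with the microfibril gene Mfap5 at 8232 ± 5767 and 4141 ± 472 CPM and the hyaluronan receptor Cd44 at 272 ± 124 and 408 ± 28.9 CPM. Interstitial progenitor markers were negative in 8 of 13 (-0.02, adjusted p = 0.362), with Efhd1 at 76.3 ± 52.9 and 33.6 ± 7.03 CPM. Committed preadipocyte markers were negative in 11 of 14 (-0.27, adjusted p = 0.178). Their member Fabp4 was at 471 ± 427 and 170 ± 9.12 CPM, and its log2 fold change of -1.47 became 0.02 without WT 2. Collagen and matrix genes were negative in 17 of 25 (-0.23, adjusted p = 0.215), with the inhibitor Timp1 at 376 ± 282 and 163 ± 26.4 CPM (SD, n = 2). Log2 fold changes of the other named genes also depended on single libraries. With a library left out they ranged from -1.57 to -2.2e-04 for Mfap5, 0.19 to 1.15 for Cd44, -1.75 to -0.21 for Efhd1 and -1.81 to -0.11 for Timp1.

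Signalling and stress lists did not pass the main test either. Glucocorticoid response genes were negative in 13 of 15 (median -0.78, camera adjusted p = 0.058), with Cdkn1a at 171 ± 44.0 CPM in WT and 77.5 ± 21.2 CPM in KO-labelled libraries and the opposite sign for Tsc22d3, at 73.7 ± 14.9 and 119 ± 17.4 CPM (SD, n = 2). The glucocorticoid list passed as lower in 4 of 19 alternatives, with DESeq2 (adjusted p = 0.0325), no filter (0.0418), without WT 1 (0.0341) and without Per3 KO 2 (0.0299), the highest being 0.697. Immediate early genes were negative in 14 of 19 (-0.35, adjusted p = 0.109), with Jun at 79.3 ± 27.6 and 41.5 ± 4.80 CPM. The inflammatory list was negative in 10 of 17 (-0.47, adjusted p = 0.145) and the interferon list positive in 12 of 19 (0.30, adjusted p = 0.384). Without WT 1 the interferon list passed as higher (adjusted p = 0.000689), and without WT 2 it turned to lower (0.116), with 0.851 as the highest of 19 alternatives. Unfolded protein response genes were negative in 12 of 16 (-0.24, adjusted p = 0.217), TGF-beta and BMP genes in 12 of 16 (-0.29, adjusted p = 0.178) and Wnt genes in 9 of 17 (-0.07, adjusted p = 0.813). Oxidative phosphorylation genes were negative in 16 of 22 (-0.36, adjusted p = 0.129), and passed as lower without WT 1 (adjusted p = 0.0281), with 0.982 as the highest of 19 alternatives. Branched-chain amino acid catabolism was positive in 10 of 20 (0.01, adjusted p = 0.491), with Hibch at 12.1 ± 9.26 and 30.7 ± 9.20 CPM. The smallest adjusted p of any list with an estimated correlation was 0.682.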

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

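DESeq2 size factors in edgeR and the crossed block were chosen after seeing the data. The limma fit with a pseudocount of 0.5 was the first branch of the design fixed beforehand, for FPKM values. It became an alternative once the tables were seen to hold counts. The count of 0 genes past the threshold became 1 in each of the 7 limma settings, with a mean RPKM of at least 5 and with the replicate block, 4 without a filter (3 higher, 1 lower) and 14 with DESeq2. It was 1 to 4 with a library left out, with 4 without WT 1, 1 without WT 2 or Per3 KO 1, and 3 without Per3 KO 2, where the liver transcripts Alb and Apoa2 were called lower. DESeq2 size factors in edgeR gave 0. Gm5506 passed in 16 of 17 gene-level alternatives, with adjusted p from 4.57e-26 to 0.289. The threshold with a log2 fold change of at least 1 gave 0. The cause of these differences was not tested. On the 8290 genes of the limma fits the median log2 fold change was 0.27 for RPKM as deposited, 0.03 with TMM scaling and -0.00302 with quantile scaling, so the shift goes with leaving out a scaling between libraries.

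Replicate numbers were not taken as pairs, since the labels state no pairing. Same-numbered libraries did not deviate together (r = -0.142 across genes), which cannot exclude pairs. The replicate block called 1 gene, Gm5506, and 3 lists. The crossed block called 2 genes and 4 lists.

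The count of lists past the threshold, 3, became 1 with a pseudocount of 0.1 and with a mean RPKM of at least 5, 6 without a filter, and 0 with an estimated correlation or fry. It was 0 to 7 with a library left out (7 without WT 1, 0 without WT 2, 1 without Per3 KO 1). The clock list had adjusted p = 0.0532 with a pseudocount of 0.1, 0.682 with an estimated correlation and 0.579 with fry, and 0.0134 to 0.0832 with a library left out. Cell cycle had 0.0748 with a mean RPKM of at least 5, 0.682 with an estimated correlation and 0.697 with fry, and 1.1e-11 to 0.792 with a library left out, turning to lower without Per3 KO 1 (0.792). Cholesterol synthesis had 0.0687 with limma (also with no trend or a robust fit), 0.0816 and 0.0689 with pseudocounts of 0.1 and 1, 0.0728 with DESeq2, 0.682 with an estimated correlation and 0.697 with fry, and 2.68e-08 to 0.792 with a library left out, turning to lower without WT 2 (0.290).

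The Wnt list turned to higher with limma (adjusted p = 0.579, also with no trend or a robust fit), pseudocounts of 0.1 (0.492) and 1 (0.637), TMM (0.628) or quantile (0.634) scaling and no filter (0.899). Quantile scaling turned the precursor list (0.423) and the collagen list (0.396). Hbb-b1 turned to -0.0169 with a pseudocount of 0.1, -0.10 with quantile scaling, -0.42 with the replicate block and -0.41 with the crossed block.

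With a library left out, the log2 fold change changed sign, with these ranges, for Per3 (-0.17 to 1.28), Ly6a (-2.27 to 0.19), Pecam1 (-0.57 to 1.53), Klf2 (-1.41 to 0.19), Fabp4 (-2.18 to 0.0160), Mmp14 (-1.55 to 0.0362), Dusp1 (-1.49 to 0.18), Bmp4 (-1.69 to 0.20), Saa3 (-3.11 to 0.42), Ndufa4 (-1.76 to 0.46), Cox7a2 (-1.70 to 0.40), Creld2 (-2.69 to 0.22), Ly6c1 (-2.30 to 0.0682), Eng (-1.22 to 0.32), Krt19 (-1.62 to 0.41), Krt18 (-4.45 to 8.98), Hbb-b2 (-1.79 to 2.30), Hbb-b1 (-2.34 to 1.43), Acta1 (-1.26 to 0.31) and Cry1 (-1.04 to 0.0672). The other lists that turned had adjusted p ranges of 0.0581 to 0.752 (anti-adipogenic), 0.162 to 0.850 (mature adipocyte), 0.705 to 0.981 (Wnt), 0.000689 to 0.851 (interferon), 0.313 to 0.981 (branched-chain amino acid), 0.000831 to 0.422 (leukocyte), 0.335 to 0.679 (endothelial) and 0.422 to 0.978 (Schwann). Without WT 2 there were 11 of 108 named genes and 8 of 25 lists that turned, more than without any other library. Depth limits genes near the floor, such as Klf15 in the WT libraries.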

Other observations

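Several transcripts outside the named groups separated the groups in all 4 libraries, chosen here after their values were seen and none past edgeR's threshold. Myoc, which encodes myocilin, had 286, 329, 23 and 35.91 reads in WT 1, WT 2, Per3 KO 1 and Per3 KO 2, and was among the 14 genes that DESeq2 called. The kinesin gene Cenpe had 3, 4, 335 and 312 reads and was also among them, although DESeq2 made 81 false calls in simulated data of this spread. In the imprinted cluster that holds Rian, the deiodinase gene Dio3 had 112, 42, 0 and 0 reads, while Meg3 and Mirg had log2 fold changes of 0.31 ± 0.65 and 0.09 ± 0.48 (SE).

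Of the tests below, those of the clock genes, those of Gm5506 and the test of genotype for liver transcripts were chosen after the result was seen, and the test of liver genes not yet looked at was written before.

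In the clock list, the output arm (7 genes, all higher, median 2.26) and the genes in antiphase (5, all lower, median -0.79) differed by 3.04 on the log2 scale, against 0.762 at the 95th percentile of 10000 random lists matched on expression (permutation p = 1e-04, the smallest they can give). The arms were set after the values were seen, so this p does not test a pattern named beforehand. This p also came from exchanging genes, not the labels of libraries, so it does not measure the spread between libraries. With 2 libraries per group, exchanging labels could not give a p this small. Clock genes may move together while random genes need not, so the random lists may vary too little and this p may be too small. With each library left out in turn, the difference stayed between 2.78 and 3.42. The 95th percentile of random lists in these fits was at most 1.29. With all libraries thinned to the smallest total the difference was 3.08. The difference between these arms was thus present without each single library and at equal depth. Since the arms were chosen for this pattern, these values cannot decide whether a single library or depth made it. Within the arms, Cry1 turned to 0.07 without WT 1. The whole clock list, fixed before the data were examined, lost its camera call without WT 2 and without Per3 KO 1. Its adjusted p ranged from 0.00201 to 0.682 over its alternatives. The arm difference without WT 2 and without Per3 KO 1 was 2.78 and 3.42. With arms set after the values were seen, it does not outweigh the lost calls of the fixed list. A hypothesis that stays undecided is that the groups may have differed in clock phase at collection. The labels put all 4 libraries at ZT2, so with a single time point phase and genotype cannot be told apart, and a time series in both genotypes would be needed.

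Gm5506 had reads almost only in the KO-labelled libraries. The sum of Eno1 and Gm5506 still differed by 3.81 ± 1.17 (log2, SE), with 616, 19.996, 5704 and 7361 reads in WT 1, WT 2, Per3 KO 1 and Per3 KO 2, so a mere passing of reads between both copies does not account for it. Genes within 5 Mb of Per3 (103 tested) had a median size of log2 fold change of 0.517, between 0.406 and 0.601 (5th and 95th percentile of random lists), but Gm5506 lies on chromosome 18, so this test could not decide anything about it. The transcripts are 99.5% identical over 1652 bases, with 9 mismatches, so reads of Eno1 can match both copies. How reads that match several genes were treated is not given, so where such reads were counted is unknown. Eno1 starts 766 kb from Per3. A hypothesis that counts cannot test is that another strain's Eno1 allele travels with the Per3 allele and changes where these reads are placed. The sequences of reads over both genes would be needed, and a real difference in expression is also open.

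Transcripts typical of liver did not follow the groups, with 3290, 183, 1 and 30330 reads of Alb in WT 1, WT 2, Per3 KO 1 and Per3 KO 2. Summed over 30 liver genes the level was 769, 162, 217 and 2379 CPM in the same order. Most of the sum in Per3 KO 1 came from Vtn (4806 reads) and Trf (3487) among these genes. Over the 25 of these not looked at before, the median log2 ratio of Per3 KO 2 to Per3 KO 1 was 7.07, with 24 higher, as RNA from liver cells or from a liver library may give, although the sort on Sca1 should leave out hepatocytes and Cps1, abundant in liver, had 21 reads in Per3 KO 2. Per3 KO 1 had a median log2 ratio of -4.85 to the WT mean (29 of 30 lower), which rests on WT 1. Against WT 2 alone the median was -1.83 over the 20 genes above 3 reads in either library (17 lower, upper quartile -0.64), which argues against genotype as the whole cause, although Vtn (1129 and 4806 reads in WT 2 and Per3 KO 1), Trf (721 and 3487) and Apoa1 (4 and 10) were higher. Of the 30 genes, 6 had at least 50 reads in Per3 KO 1 and may be expressed by the precursors themselves, and where the RNA came from stays open.

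WT 2 had the lowest mean correlation with the other libraries, 0.809. Depth and transcript length were first tested as explanations for it, and this pattern was set aside for the liver transcripts after those results were known. After thinning to equal totals the mean correlation of WT 2 was 0.816, against 0.843 to 0.862 in the other libraries. The rank correlation across genes of its deviation with relative transcript length was -0.115, against 0.0374 in WT 1, -0.141 in Per3 KO 1 and 0.239 in Per3 KO 2. No biological explanation was tested.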
